A study of Mus musculus with 6 samples.

How the data were processed

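RNA was sequenced in 6 samples of NMuMG mouse mammary epithelial cells under TGF-beta at day 4, 3 given siRNA against Mnt and 3 given a non-targeting siRNA. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with standard Illumina protocols, which do not say whether strand was kept. The submitters' processing notes name TopHat2 2.1.0, DESeq2 and the mouse genome build mm9. The tool that counted reads per gene, the gene annotation, the treatment of reads that match several genes and any filter are not given in the sources used here. Genes are named by symbol as in the deposited table, which gives no coordinates, and none are given here.

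The authors deposited 1 table of normalised values for 14526 genes in 6 libraries, and its unit is a signal that is never negative. From the values themselves, each deposited value is a read count divided by 1 size factor per library and written with 6 significant digits. Dividing by the value of 1 read in each library, found from the low values, returned whole reads: 99.75% of the values above 0 lay within 0.05 read of a whole number. The recovered totals were 32418904, 24767602 and 42193292 reads for siNTC replicates 1, 2 and 3 and 25666005, 22323050 and 22336675 for siMnt replicates 1, 2 and 3. The table covers genes with at least some reads, the lowest gene mean being 1.3, and how those genes were chosen is not given in the sources used here. Because the normalisation is 1 factor per library, it cannot remove a trend with GC content or transcript length, and a change in the total RNA per cell would not be seen. No 2 libraries were copies: the mean chi-square per gene between replicates was 15.2 or more.

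Samples were grouped by the titles, which also give the replicate numbers. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Values were taken as log2(value + 1), genes with a mean under 10 over the 6 libraries were left out (1958 genes), and the remaining 12568 were tested with limma 3.58.1 in R 4.3.3, using empirical Bayes with a trend, on all 6 libraries and with no block. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale understate the change of genes near 0. The design assumed normalised values or counts and was kept as written for this unit. 23 gene lists and 6 lists of cell type markers were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The estimated correlation and fry rest on 4 residual degrees of freedom, or 2 with the replicate number as a block. Their power is limited, least with the block, so a list that does not pass there is not shown to be unchanged. List members absent from the table, Epcam, Cldn3 and Cldn7 among them, were not analysed here. The genes named are Mnt; the 8 with the largest rise and the 8 with the largest fall among those that passed with groups that do not overlap and a mean of at least 50 in the higher group; the 3 members with the smallest adjusted p of each list with a passing member; the 2 most expressed members of each other list with at least 5 tested members; and every tested member of the Max and Mlx network. That gave 94 genes, and a gene named outside the rule is said to be so. The values of 2 single genes are not reported here, and 1 of them was left out of a group chosen after the data were seen.

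Same-numbered libraries deviated together: the correlations of their deviations from the group means, across genes, were 0.28, 0.50 and 0.35 for numbers 1, 2 and 3. Every other pair lay between -0.38 and 0.03, so each library correlated best with its own number. Deviations within a group cancel out, so a positive correlation for the same number pushes the other pairs lower. With so few libraries few pairings are possible, and the numbered one could correlate best by chance. The pairing comes from the data and the replicate numbers of the titles; the labels do not say what the numbers share. The fit with the replicate number as a block was planned as an alternative, and its values are given beside many of the calls and counts that it changes.

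Alternatives were other pseudocounts, filters, scalings and variance models, the block, leaving out each library, other thresholds, and count tests on the recovered reads (edgeR 4.0.16 quasi-likelihood with TMM, and DESeq2 1.42.0). A correction for GC content and transcript length (loess trends per library, from the longest transcript of each symbol in GENCODE M21, a different build used here only for these properties, which matched 98.8% of the tested genes) and thinning of all libraries to the lowest total were added after seeing the data. Tables were prepared with Python 3.11.15 and pandas 2.3.3. The scripts were tested on simulated reads for this comparison, 12508 genes with the real means and library sizes: limma recovered 9% of genes changed by 1.5-fold, 58.2% of those changed by 2-fold and 90.9% of those changed by 4-fold, with 8 false calls among 113. In the same simulation camera called the 1 raised list and 0 of 20 unchanged lists. The simulation gives each gene its own noise and does not hold the shared shifts between libraries that the real data show.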

Results

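Gene expression was measured by RNA sequencing in NMuMG cells, an epithelial line from normal mouse mammary gland that loses its epithelial form and takes on a mesenchymal one when given TGF-beta (epithelial to mesenchymal transition, EMT). Per the labels' protocols, cells were plated at equal density, TGF-beta and small interfering RNA (siRNA) were given together after 16 hours, and both were renewed on day 2. 3 libraries came from cells that received siRNA against Mnt (siMnt) and 3 from cells that received a non-targeting control (siNTC), all taken at day 4 of TGF-beta. Each library held between 22323050 and 42193292 reads assigned to the 14526 genes of the table, and 12568 genes had a mean of at least 10 normalised read counts and were tested. Libraries from cells without TGF-beta were not analysed here, so every difference below is between siRNAs in cells under TGF-beta. Values are normalised read counts, given as mean ± SD over n = 3 libraries per group, siNTC first and siMnt second. Log2 fold changes are siMnt minus siNTC on the log2(value + 1) scale with their standard error, and adjusted p-values are from limma with Benjamini-Hochberg adjustment over all tested genes.

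The comparison asked which genes change in cells under TGF-beta when Mnt is lowered. Mnt is a transcriptional repressor that pairs with Max and binds the same E-box sequences as Myc. In siMnt cells, 10 of 26 tested genes of glycolysis and the hypoxia response rose, Bnip3 and Ldha among them, as did 6 of 22 of cholesterol synthesis, Insig1 among them. As lists both were higher by a set test with a preset correlation, but not with an estimated correlation or by a rotation test with the replicate number as a block. The tests that did not pass rest on few residual degrees of freedom (4, or 2 with the block) and have limited power. Of 23 tested epithelial identity genes 2 rose, Muc1 and Ehf. The intermediate filament gene Vim, the matrix protease Mmp9, the cytokine Il11, the smooth muscle actin-binding protein Cnn1 and the EMT transcription factor Zeb2 fell. Zeb2 was alone among 18 tested EMT factors, and Cnn1 was 1 of 2 that fell among 24 actin and contractile genes. The receptor tyrosine kinase Axl and the calcium-binding protein S100a4, both also mesenchymal markers, rose. No gene passed by limma without siNTC replicate 1, siMnt replicate 1 or siMnt replicate 2. Mnt itself was present at 50.4% of the control level, from 1269 ± 352 to 639.7 ± 98.5 normalised read counts. The 3 siNTC libraries held 1316, 896 and 1596 and the 3 siMnt libraries 613, 557 and 749, so the groups did not overlap. Within replicate numbers 1, 2 and 3 the siMnt value was 46.6%, 62.2% and 46.9% of the siNTC value. The log2 fold change -0.96 ± 0.22, adjusted p = 0.0546 (limma), lay just outside the threshold of 0.05, and with the replicate number as a block the adjusted p was 0.00442. Without siNTC replicate 2 the log2 fold change was -1.19 with adjusted p = 0.0393, and without siNTC replicate 3 it was -0.77 with adjusted p = 0.041. Mnt did not pass in limma without siNTC replicate 1 (adjusted p = 0.188) or siMnt replicate 1, 2 or 3 (0.225, 0.209 and 0.0902). With all libraries edgeR gave adjusted p = 0.052 and DESeq2 0.0014. An exact two-sided permutation test on Mnt alone gave p = 0.1, the smallest that 3 against 3 libraries allow.

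The libraries separated by siRNA along the first principal component, which held 60.8% of the variance, with siNTC replicate 3 standing apart from its group. The 3 siMnt libraries lay at 35.5, 31.1 and 29.4 and siNTC replicates 1 and 2 at -43.0 and -52.3, whereas siNTC replicate 3 lay at -0.81. Over all tested genes its Pearson correlation of log2 values, which is across genes and not across replicates, was 0.987 with siMnt replicate 3, against 0.979 and 0.963 with the other siNTC libraries. Its Mnt level was the highest of all 6 libraries. Il11 and Mmp9 were lowest there among the controls. Bnip3, Axl and Hdac1 in this library were close to the other controls.

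**Figure D1:**
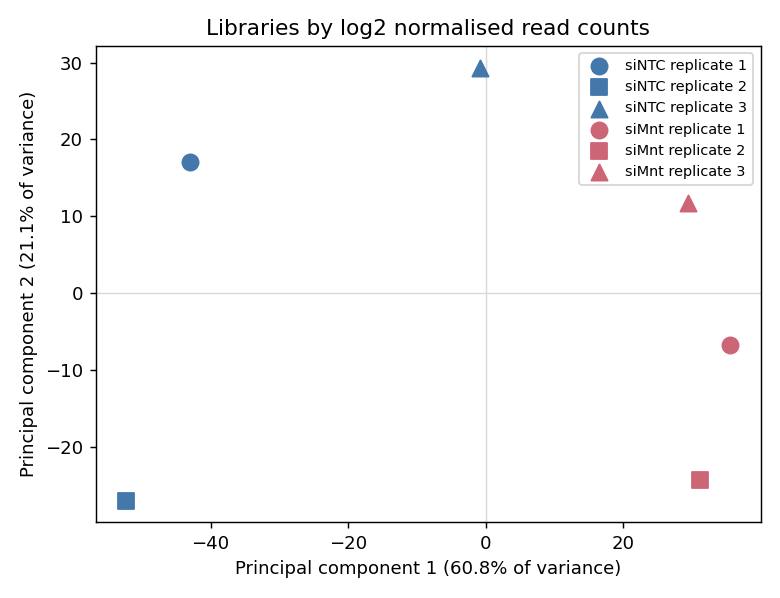
Principal components 1 and 2 of the log2 normalised read counts of the 12568 tested genes, 1 point per library, with colour for the siRNA and shape for the replicate number. The 3 siMnt libraries lie at the right, between 29.4 and 35.5 on component 1, and siNTC replicate 3 lies at -0.81, between them and the other controls.

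At an adjusted p under 0.05 (limma), 494 of the 12568 tested genes differed between siMnt and siNTC, 322 higher and 172 lower in siMnt, and 320 of them by at least 2-fold. Among the genes with the largest rise were the scavenger receptor Cd36 (from 9.58 ± 5.60 to 236 ± 123; log2 fold change 4.46 ± 0.55, adjusted p = 0.0155), the retinaldehyde dehydrogenase Aldh1a1 (from 305 ± 180.1 to 3011 ± 948; log2 fold change 3.42 ± 0.42, adjusted p = 0.0155), the perforin-like Mpeg1 (from 21.1 ± 13.2 to 287 ± 71.9; log2 fold change 3.83 ± 0.41, adjusted p = 0.0116) and haptoglobin, Hp (3.42). Cxcl15, Sptssb, Cbln3 and Ppp1r9a also rose, with log2 fold changes of 4.76, 4.57, 3.71 and 3.57. Among those with the largest fall were the stathmin Stmn4 (from 318 ± 277 to 2.34 ± 1.25; log2 fold change -6.01 ± 0.86, adjusted p = 0.0195), Mmp9 (from 153 ± 82.3 to 8.08 ± 1.43; log2 fold change -3.89 ± 0.49, adjusted p = 0.0162), Il11 (from 3152 ± 2048 to 214 ± 65.0; log2 fold change -3.57 ± 0.59, adjusted p = 0.0264) and the retinol dehydrogenase Rdh10 (from 16977 ± 6848 to 2256 ± 227; log2 fold change -2.82 ± 0.30, adjusted p = 0.0116). Lce1g, Clca4b, Orm2 and Cmah fell too, with log2 fold changes of -4.89, -3.34, -3.17 and -2.89, and Lce1g, Clca4b and Orm2 belong to families of near-identical genes, so their values are uncertain. In all 494 genes the groups did not overlap, which held for 31.5% of the tested genes, against 10% by chance. With the replicate number as a block 1998 genes passed, 1173 higher and 825 lower, and all 494 were among them. The block leaves each log2 fold change as it was, so their direction could not differ. Of the 1998, 506 were higher and 193 lower by at least 2-fold. edgeR on recovered reads called 445, of which 436 were shared. After a correction for GC content and transcript length, chosen after seeing the data, 1014 genes passed, 510 higher and 504 lower, so that the share of higher genes was 50.3% in place of 65.2%. The count depended on single libraries: limma called 2012 genes without siNTC replicate 3, 217 without siNTC replicate 2 and 125 without siMnt replicate 3. It called 0 without siNTC replicate 1, siMnt replicate 1 or siMnt replicate 2, where 2193, 1816 and 1920 genes had an unadjusted p under 0.05. In these fits edgeR called 0 each, and DESeq2 called 710, 447 and 554. Of the 51 genes that passed and were chosen by the fixed rule, 51 passed without siNTC replicate 3, 30 without siNTC replicate 2 and 17 without siMnt replicate 3.

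**Figure D2:**
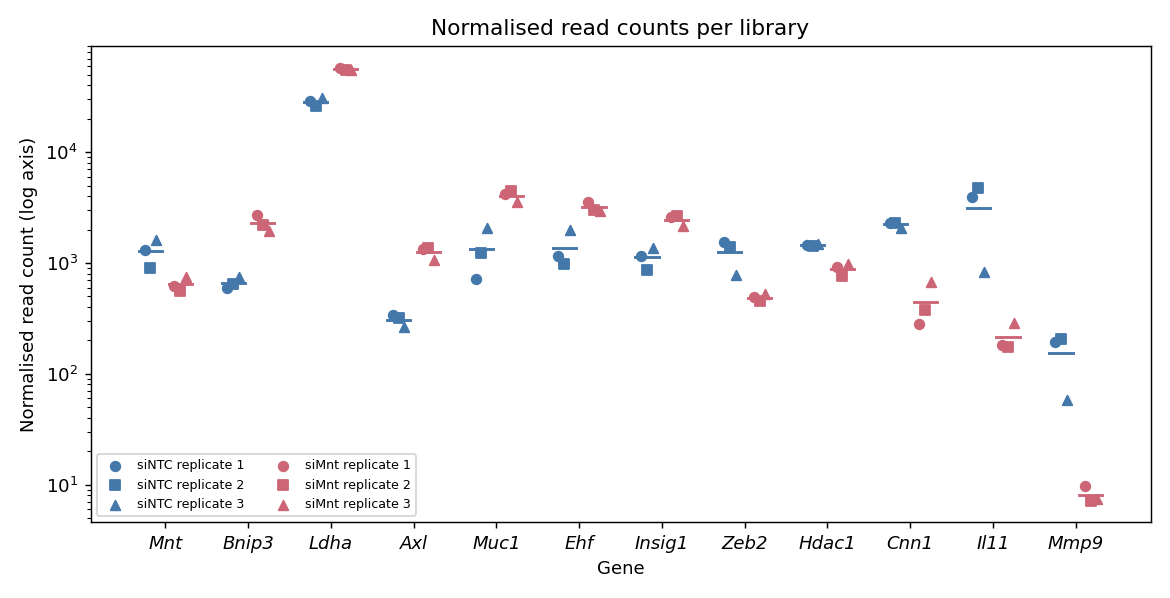
Normalised read counts of 12 genes in each library on a log axis, with colour for the siRNA, shape for the replicate number and a bar at the mean of each group. Bnip3, Ldha, Axl and Insig1 are higher in each siMnt library than in any siNTC library, and for Il11, Mmp9 and Zeb2 the third siNTC library lies between the other controls and siMnt.

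Genes of glycolysis and the hypoxia response formed the list with the smallest p-value by camera. Of its 26 tested members 10 rose and 0 fell over all genes tested, 18 rose adjusted over the list alone, and 16 did not pass. Bnip3, a mitochondrial BH3-domain protein induced by hypoxia, rose from 663 ± 76.9 to 2276 ± 400.3 (log2 fold change 1.77 ± 0.16, adjusted p = 0.0107). Ldha, lactate dehydrogenase, rose from 28652 ± 2282 to 56103 ± 1664 (log2 fold change 0.97 ± 0.14, adjusted p = 0.02), and Aldoa, aldolase, rose from 25939 ± 1749 to 47924 ± 1159.7 (log2 fold change 0.89 ± 0.13, adjusted p = 0.0221). Aldoa and Ldha have near-identical retrocopies. Those of aldolase, Aldoart1 and Aldoart2, named outside the rule after their values were seen, also passed, with log2 fold changes of 0.90 and 0.84, so part of these reads cannot be assigned to a single gene. The list median was 0.61, and within replicate numbers 1, 2 and 3 it was 0.69, 0.55 and 0.56. By camera, limma's competitive set test with a preset correlation of 0.01, the list was higher (adjusted p = 3.6e-10 over 23 lists; adjusted p = 0.21 with an estimated correlation), and fry, a rotation test of the set by itself, gave adjusted p = 0.00603. With the replicate number as a block fry gave adjusted p = 0.131, outside the threshold. Without siMnt replicate 3 only 2 members passed, and 0 passed without siNTC replicate 1, siMnt replicate 1 or siMnt replicate 2.

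Of 22 tested genes of cholesterol synthesis 6 rose and 0 fell, 9 rose adjusted over the list alone, and 16 did not pass. Insig1, a sterol-regulated protein of the endoplasmic reticulum, rose from 1130.2 ± 253 to 2466 ± 269 (log2 fold change 1.14 ± 0.18, adjusted p = 0.0242). Mvd and Pmvk, a decarboxylase and a kinase of the mevalonate pathway, rose by log2 fold changes of 0.86 and 0.70 (adjusted p = 0.0206 and 0.0264). The list median was 0.32 (camera adjusted p = 3.1e-07, or adjusted p = 0.795 with an estimated correlation; fry adjusted p = 0.037). With the replicate number as a block 10 members rose, and fry gave adjusted p = 0.131. Without siMnt replicate 3, and without siNTC replicate 1, siMnt replicate 1 or siMnt replicate 2, 0 members of this list passed.

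Of the epithelial identity list, 2 of 23 tested members rose, 0 fell and 21 did not pass, with 3 rising adjusted over the list alone. Those 2 were Muc1, a mucin of the apical surface (from 1338 ± 682 to 4039 ± 467; log2 fold change 1.72 ± 0.33, adjusted p = 0.0368), and Ehf, an epithelial ETS factor (from 1374 ± 536 to 3176 ± 325; log2 fold change 1.27 ± 0.24, adjusted p = 0.0368). Cdh1, which encodes E-cadherin and was looked at outside the fixed rule, was at 7543 ± 2429 and 10572 ± 729.6 (log2 fold change 0.53 ± 0.21, adjusted p = 0.179), with adjusted p = 0.0474 under the block and 0.00691 without siNTC replicate 3. Cdh1 did not pass when any other single library was left out. The list median was 0.38, and 0.45, 0.45 and 0.07 within replicate numbers 1, 2 and 3 (camera adjusted p = 0.02; adjusted p = 0.86 with an estimated correlation; fry adjusted p = 0.282). With the block 7 members rose and 1 fell over all genes, and 12 rose and 2 fell adjusted over the list alone. Without siNTC replicate 3, which lay near siMnt for this list, 11 rose and 1 fell. Without siNTC replicate 2 or siMnt replicate 3, 0 passed, and the camera adjusted p without siNTC replicate 2 was 0.0527. Desmosome and hemidesmosome genes did not pass by camera (adjusted p = 0.0966; 0.034 with the block; 0.0379 without siMnt replicate 2). The call with the block was lost with an estimated correlation (0.931) and by fry (0.315). By limma 0 of 14 tested members passed over all genes (6 had an unadjusted p under 0.05, edgeR called 1 and DESeq2 5). Adjusted over the list alone 4 were higher and 1 lower, and over all genes under the block 4 and 1. The desmosomal linker Dsp was at 8208 ± 2418 and 14888 ± 2901 (adjusted p = 0.081; 0.00877 with the block). Of the tight junction, adherens junction and polarity genes 1 of 24 rose, Amot (from 651 ± 114 to 1304 ± 228; adjusted p = 0.0323), with 1 higher and 1 lower adjusted over the list alone. With the block 2 rose and 2 fell, without siNTC replicate 3, 4 rose and 2 fell, and without siMnt replicate 3, 0 passed. Over all 12568 tested genes 1998 passed with the block and 2012 without siNTC replicate 3. Counts near that share are not particular to a list. Of the keratins 1 of 9 rose, Krt23 (from 71.9 ± 17.2 to 232 ± 50.4; log2 fold change 1.68 ± 0.26, adjusted p = 0.0226), with 1 higher and 2 lower adjusted over the list alone. Neither list passed by camera (adjusted p = 0.542 and 0.949).

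The mesenchymal list split. Of its 25 tested members 4 rose, 5 fell and 16 did not pass; adjusted over the list alone 7 rose and 12 fell. Axl rose from 305 ± 38.9 to 1258 ± 178 (log2 fold change 2.04 ± 0.16, adjusted p = 0.0107), with log2 differences of 2.00, 2.11 and 2.01 within replicate numbers 1, 2 and 3. The lysyl oxidase Loxl2 rose from 637 ± 81.6 to 2532 ± 829.8 (log2 fold change 1.94 ± 0.24, adjusted p = 0.0155) and S100a4 rose from 1999 ± 215 to 5363 ± 715 (log2 fold change 1.42 ± 0.14, adjusted p = 0.0107). The others, named after their values were seen, were the collagen chaperone Serpinh1, which rose from a low level (from 8.32 ± 5.39 to 67.3 ± 15.1), and Vim, tenascin C (Tnc), Mmp2 and N-cadherin (Cdh2), which fell with log2 fold changes of -1.81, -1.58, -2.14 and -0.74, with Mmp9 the fifth gene to fall. Vim fell from 39813 ± 10695 to 11565 ± 4167 (log2 fold change -1.81 ± 0.28, adjusted p = 0.0226). Camera gave adjusted p = 0.376 for the list as a whole. With the block 7 rose and 12 fell. Without siNTC replicate 3, 6 rose and 12 fell, without siNTC replicate 2, 3 rose and 4 fell, and without siMnt replicate 3, 3 rose and 3 fell.

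Among EMT transcription factors, Zeb2, a zinc finger repressor of E-cadherin, fell from 1243 ± 402 to 487 ± 33.7 (log2 fold change -1.29 ± 0.24, adjusted p = 0.0353), alone of 18 tested members over all genes and adjusted over the list alone. Zeb1 was at 2111 ± 457 and 1329 ± 101 (adjusted p = 0.0763; 0.012 with the block). With the block 4 members fell over all genes and 7 adjusted over the list alone. Without siNTC replicate 3, 4 fell, and 0 passed without siNTC replicate 2 or siMnt replicate 3. Of the TGF-beta and SMAD targets 1 of 28 rose, the dominant negative helix-loop-helix factor Id1 (from 1713 ± 144 to 3102 ± 258; log2 fold change 0.86 ± 0.12, adjusted p = 0.0185), and 2 fell, Il11 and the cyclin-dependent kinase inhibitor Cdkn2b (log2 fold change -0.71 ± 0.14, adjusted p = 0.0417). Adjusted over the list alone 1 rose and 4 fell. With the block 3 rose and 8 fell, without siNTC replicate 3, 2 rose and 10 fell, and without siNTC replicate 2 or siMnt replicate 3 Id1 alone passed. Neither list passed by camera (adjusted p = 0.175 and 0.185), although the second did without siNTC replicate 3 with the preset correlation (adjusted p = 0.00446). With all libraries the second gave 0.959 with an estimated correlation and 0.742 by fry. Of the TGF-beta pathway components 1 of 22 rose, the ligand Bmp4 (from 172 ± 32.5 to 332 ± 51.8; log2 fold change 0.95 ± 0.20, adjusted p = 0.0448), with 2 higher and 2 lower adjusted over the list alone. Camera gave adjusted p = 0.647. With the block 4 rose and 2 fell, and without siNTC replicate 3 the counts were 4 and 2. Without siNTC replicate 2 or siMnt replicate 3, 0 passed.

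Of 24 tested actin, contractile and serum response factor target genes 2 fell, 0 rose and 22 did not pass, with 6 falling adjusted over the list alone. Calponin, Cnn1, fell from 2234 ± 140.3 to 444 ± 201 (log2 fold change -2.42 ± 0.28, adjusted p = 0.0155) and the LIM protein Pdlim7 fell from 2937 ± 657 to 1494 ± 231 (log2 fold change -0.96 ± 0.19, adjusted p = 0.0414). The alpha-actinin Actn1 was at 21829 ± 6478 and 11728 ± 856 (adjusted p = 0.0621; 0.0134 with the block). The list median was -0.33 (camera adjusted p = 2.4e-04; adjusted p = 0.86 with an estimated correlation; fry adjusted p = 0.334). Within replicate numbers 1, 2 and 3 it was -0.48, -0.61 and 0.03, siNTC replicate 3 being near siMnt for these genes. 7 members fell with the block, 11 without siNTC replicate 3, and 1 without siNTC replicate 2 or siMnt replicate 3. Of 29 tested integrin and matrix genes 1 rose and 4 fell, with 5 rising and 9 falling adjusted over the list alone. The collagenase Mmp13 rose from 380.1 ± 239 to 1461 ± 183 (log2 fold change 2.103 ± 0.36, adjusted p = 0.0288), while fibulin 2, Fbln2, fell from 54448 ± 9987 to 20995 ± 3505 (log2 fold change -1.37 ± 0.19, adjusted p = 0.0185) and fibrillin 1, Fbn1, fell with a log2 fold change of -1.19. Camera gave adjusted p = 0.345. With the block 5 rose and 9 fell, without siNTC replicate 3, 4 rose and 9 fell, and without siMnt replicate 3, 0 rose and 1 fell.

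Of 34 tested genes of ribosome biogenesis 2 fell, 0 rose and 32 did not pass, both over all genes and adjusted over the list alone. A negative log2 fold change was found for 32 of the 34. Heatr1 (from 1873 ± 275 to 1117 ± 113; log2 fold change -0.74 ± 0.15, adjusted p = 0.0411) and Utp20 (from 2393 ± 351 to 1514 ± 149.7; log2 fold change -0.65 ± 0.15, adjusted p = 0.0493), both factors of small subunit processing, were those that fell. The list median was -0.46 (camera adjusted p = 2.1e-07; adjusted p = 0.86 with an estimated correlation; fry adjusted p = 0.334). Within replicate numbers 1, 2 and 3 it was -0.51, -0.77 and -0.09. With the block 12 members fell over all genes and 21 adjusted over the list alone. Without siNTC replicate 3, 19 fell, and without siNTC replicate 2 or siMnt replicate 3, 0 passed. Of the Max and Mlx network 1 of 12 tested members rose, the Myc antagonist Mxi1 (from 2316 ± 348 to 3534 ± 23.3; log2 fold change 0.62 ± 0.13, adjusted p = 0.0478), with 2 higher and 1 lower adjusted over the list alone. Myc was at 4859 ± 3009.8 and 2425 ± 1235 (log2 fold change -0.90 ± 0.50, adjusted p = 0.312; adjusted p = 0.0135 with the block and 0.0414 without siNTC replicate 3), Mycn at 84.6 ± 15.5 and 167 ± 38.5 (adjusted p = 0.0701; 0.0245 with the block) and Max at 949 ± 109 and 895 ± 4.41 (adjusted p = 0.757). Mlx, Mlxip and Mga, which pair with Mlx or Max, had log2 fold changes of 0.41, 0.35 and 0.23 (adjusted p = 0.161, 0.453 and 0.433). Mxd1, Mxd3, Mxd4 and Mlxipl had adjusted p-values of 0.505, 0.738, 0.668 and 0.933. Of 34 Myc E-box targets 3 rose and 0 fell, with 5 higher and 1 lower adjusted over the list alone: Ldha, the serine hydroxymethyltransferase Shmt1 (from 763 ± 89.6 to 1303 ± 62.2; log2 fold change 0.78 ± 0.13, adjusted p = 0.0264) and E2f2 (1.57). Neither list passed by camera (adjusted p = 0.542 and 0.905). With the block 2 rose and 2 fell in the network and 6 rose and 2 fell among E-box targets, and without siNTC replicate 3, 6 E-box targets rose and 5 fell.

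Cell cycle genes did not pass. 0 of 32 E2F and G1/S genes and 0 of 31 mitotic genes passed over all genes or adjusted over the list alone by limma, where 3 and 0 had an unadjusted p under 0.05. edgeR called 0 in both lists, and DESeq2 called 1 and 0. Top2a was at 14718 ± 4080.0 and 16503 ± 2708 and Mcm4 at 4014 ± 856 and 4116 ± 513 (adjusted p = 0.654 and 0.897), and Mki67 at 8145 ± 2637 and 11477 ± 2223 (adjusted p = 0.232; 0.0356 with the block). Camera gave adjusted p = 0.318 and 0.106. With the block 3 and 4 members rose, and the mitotic list passed as higher with the preset correlation (adjusted p = 0.00168). It did not with an estimated correlation and the block (0.931) or by fry with the block (0.406). With the preset correlation it also passed without siNTC replicate 1 (0.00165), siNTC replicate 2 (0.0131) and siMnt replicate 3 (0.000437), and the E2F list did without siNTC replicate 1 (0.00313). With all libraries both lists gave 0.959 with an estimated correlation and 0.833 by fry.

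Of 30 tested interferon response genes 1 rose, 0 fell and 29 did not pass, with 5 higher and 1 lower adjusted over the list alone. Ifitm3, a membrane protein that restricts virus entry and has close paralogs, rose from 54.6 ± 30.6 to 263 ± 15.5 (log2 fold change 2.38 ± 0.35, adjusted p = 0.0205), and Mx1 and Isg20 had log2 fold changes of 2.31 and 0.63 (adjusted p = 0.0599 and 0.0659; 0.028 and 0.0132 with the block). The list median was 0.39 (camera adjusted p = 1.8e-04; adjusted p = 0.86 with an estimated correlation; fry adjusted p = 0.334). Within replicate numbers 1, 2 and 3 it was 0.60, 0.56 and -0.005. With the block 6 members rose and 1 fell, and without siNTC replicate 3, 5 rose. Of 19 NF-kappaB and inflammatory genes 1 rose, Icam1, from a low level (from 8.74 ± 1.10 to 34.7 ± 9.05), and it did so adjusted over the list alone too. Ccl20 and Ptgs2 went opposite ways, with log2 fold changes of 2.45 and -1.66 (adjusted p = 0.0911 and 0.169; 0.0027 and 0.0111 with the block). With the block 3 rose and 3 fell. Of 23 corepressor and histone deacetylase genes 1 fell, both over all genes and adjusted over the list alone: Hdac1, a deacetylase of the Sin3 corepressor complex that Mnt recruits (from 1449.5 ± 22.8 to 889.9 ± 109.9; log2 fold change -0.71 ± 0.13, adjusted p = 0.0321). Hdac3 was at 2458 ± 155 and 1838 ± 44.9 (adjusted p = 0.0688; 0.0328 with the block). Of 23 unfolded protein and integrated stress genes 2 rose, Dnajb9 (0.70) and Vldlr (0.76), also adjusted over the list alone. Without siNTC replicate 2 or siMnt replicate 3, 0 passed. The block called 2 higher and 5 lower, and the list as lower (camera adjusted p = 0.376 without and 0.0301 with the block). That call was lost with an estimated correlation (0.931) and by fry (0.315), both with the block. 0 of 26 p53 target and apoptosis genes and 0 of 11 genes of the siRNA pathway passed over all genes or adjusted over the list alone. Of these 3 and 1 had an unadjusted p under 0.05, edgeR called 1 and 0, DESeq2 called 2 and 1, and the block called 2 higher and 3 lower among the p53 targets and 1 higher and 1 lower in the siRNA pathway. Camera gave adjusted p = 0.905, 0.868, 0.905 and 0.905 for the NF-kappaB, corepressor, p53 and siRNA lists.

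Camera thus called 6 of the 23 lists with the preset correlation, 0 with an estimated correlation (1 list had an unadjusted p under 0.05), and fry called 2, hypoxia and cholesterol. With the block camera called 9 and fry 0 (3 lists had an unadjusted p under 0.05). Other ways of splitting the same 6 libraries into 3 against 3, each still holding part of the siRNA difference, gave up to 14 lists by the preset test. The median, the mean and the test differed in sign for 4 lists that did not pass: the keratins (median -0.06, mean -0.18, test higher), the Myc E-box targets (-0.07, 0.05, higher), the p53 targets (-0.02, 0.00068, higher) and the NF-kappaB genes (-0.10, 0.13, higher). Without siMnt replicate 3, 0 members passed of the Max and Mlx network and the Myc E-box, NF-kappaB and corepressor lists, while 1 desmosome gene and 1 p53 target rose. Without siNTC replicate 2, 0 NF-kappaB genes passed, and 1 gene rose and 1 fell in the network. Without siNTC replicate 3, 6 desmosome genes rose and 3 fell, 1 keratin rose and 2 fell, 2 network genes rose and 2 fell, 1 NF-kappaB gene rose and 2 fell, and 2 p53 targets rose and 3 fell. In the same fit 2 corepressor genes and 1 gene of the siRNA list fell and 1 E2F gene rose. With the block 1 keratin rose and 1 fell, and 2 corepressor genes fell. Such counts are to be read against 1998 of all 12568 tested genes with the block and 2012 without siNTC replicate 3. In these lists as for all genes, no member passed without siNTC replicate 1, siMnt replicate 1 or siMnt replicate 2.

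**Figure D3:**
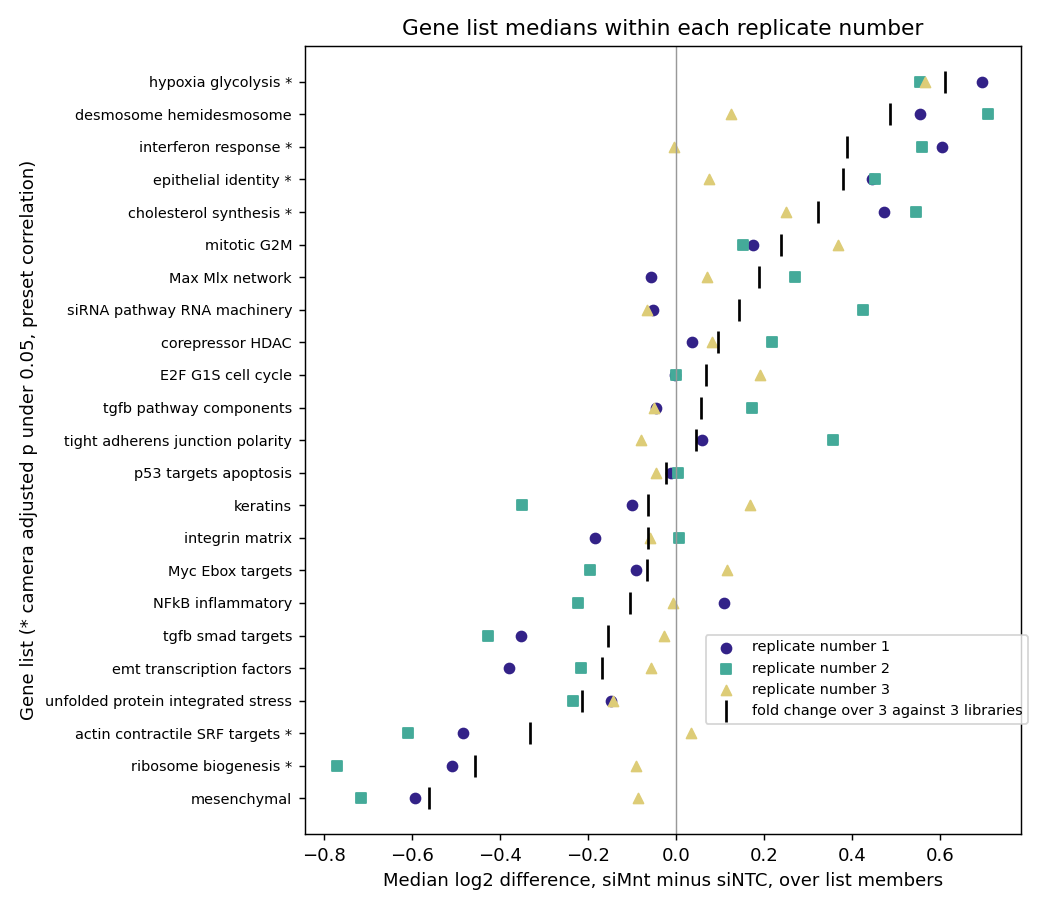
Median log2 difference between siMnt and siNTC over the tested members of each of the 23 gene lists, with 1 point per replicate number and a bar for the median log2 fold change over 3 against 3 libraries. The hypoxia and glycolysis list lies between 0.55 and 0.69 in each replicate number, whereas the actin and contractile list lies at -0.48, -0.61 and 0.03.

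Markers of other cell types were few in the table and none of the 6 lists had enough tested members for a set test. Of 3 leukocyte markers 2 rose, Csf1r, the receptor for macrophage colony stimulating factor (from 945 ± 226 to 1975 ± 110.0; log2 fold change 1.09 ± 0.17, adjusted p = 0.0242), and Itgam (1.84) from a mean of 6.02, while Cd68 was at 190.5 ± 67.8 and 164 ± 45.8 (adjusted p = 0.765). Of 2 adipocyte markers 1 rose, the fatty acid binding protein Fabp4 (from 9.05 ± 3.76 to 62.1 ± 13.6; log2 fold change 2.69 ± 0.38, adjusted p = 0.0185), and Pparg was at 9.50 ± 4.25 and 29.2 ± 8.46 (adjusted p = 0.0801; 0.0337 with the block). Of 3 basal or myoepithelial markers 1 fell, Cnn1. 0 of 3 luminal, 0 of 3 fibroblast and 0 of 2 endothelial markers passed by limma, where 0, 0 and 1 had an unadjusted p under 0.05, edgeR called 0 of each and DESeq2 called 0, 0 and 1. Adjusted over the list alone the counts were 2 leukocyte and 2 adipocyte markers higher, and 1 basal and 1 endothelial marker lower. With the block 2 adipocyte markers rose and 1 endothelial marker fell, and without siNTC replicate 3, 2 basal markers and 1 endothelial marker fell. Without siNTC replicate 2, 1 leukocyte marker passed, and without siMnt replicate 3, 0 did.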

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

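The GC and length correction, thinning, the block within edgeR, DESeq2, camera with an estimated correlation, fry or either of these, and the member counts under other settings were chosen after the results were seen; the other alternatives were planned. The 494 genes (322 higher, 172 lower) stayed within 1.5 times under both other pseudocounts, no filter, both other scalings, the robust variance model, edgeR and thinning (435 to 577), and the smallest share of these 494 called there was 427, under quantile normalization. Rescaling by median of ratios changed nothing, the values being so scaled already. No scaling moved the median of all genes by over 0.1. Of genes with few reads, the 1958 with a mean under 10 were not tested. With a minimum mean of 50 there were 322 calls (207 higher), and after thinning to equal depth 517. Without a variance trend there were 306 (212 and 94), with a 2-fold minimum 320 (91 lower), and at an adjusted p under 0.01 limma gave 0, 0 higher and 0 lower, where edgeR also gave 0, DESeq2 782, and 2938 genes had an unadjusted p under 0.05. DESeq2 gave 1457 (843 and 614). The replicate block gave 1998 (1173 and 825) in limma, 1945 (1161 and 784) in edgeR and 2141 (1248 and 893) in DESeq2, and 2093 (1243 and 850) after thinning. The GC and length correction gave 1014 (510 and 504), or 2468 (1146 and 1322) with the replicate block. Without 1 library the counts ran from 0 to 2012 in all, 0 to 1195 higher and 0 to 817 lower, the highest without siNTC replicate 3 and 0 without siNTC replicate 1, siMnt replicate 1 or siMnt replicate 2. Fewer samples may account for part of the lower counts, and the cause was not tested.

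Mnt was lower under all of them. It passed with log2 fold changes of -0.96 under the replicate block, -0.98 in DESeq2, -0.95 in edgeR and DESeq2 with the replicate block and after thinning with it, and -1.06 after the GC and length correction with and without the block, and ran from -1.19 to -0.77 without 1 library, passing without siNTC replicate 2 or 3. Beside it, the block brought 20 further named genes past the threshold and 3 further lists, ended both calls of fry, and changed no other call of limma or camera among the 51 named genes and 6 lists that had passed. In limma the block, the filters and the variance models leave each log2 fold change as it was, so they could not turn a sign. Of the 2129 values of named genes under the alternatives 18 had the other sign, none past the threshold on either side. They were Mxd3 under quantile normalization (-0.0331), Rrm1 after the GC and length correction with and without the block (-0.047), and, without 1 library, Cd68 (-0.48 to 0.059), Max (-0.15 to 0.0091), Mcm4 (-0.11 to 0.20), Mlxipl (-0.21 to 0.18), Mxd4 (-0.066 to 0.47), Plec (-0.22 to 0.57), Rrm1 (-0.17 to 0.13), Tnrc6a (-0.31 to 0.035) and Top2a (-0.034 to 0.38); the cause was not tested.

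The number of lists past the threshold was 6, 0 with an estimated correlation without and with the replicate block (1 and 0 lists had an unadjusted p under 0.05), 2 by fry, and 0 by fry with the replicate block (3 had an unadjusted p under 0.05). With 4 residual degrees of freedom, or 2 with the block, the estimated correlation and fry have limited power. A call lost there does not show an unchanged list. The estimated correlation gave camera adjusted p = 0.21 for hypoxia, 0.795 for cholesterol and 0.86 for the epithelial, actin, ribosome and interferon lists, and 0.931 for all 6 with the block; fry gave 0.282 for the epithelial list and 0.334 for actin, ribosome and interferon. With the block fry gave 0.131 for hypoxia and cholesterol, 0.406 for the epithelial, actin and ribosome lists and 0.49 for interferon. The epithelial list ran from 0.00446 to 0.0527 without 1 library, missing the threshold without siNTC replicate 2. The other 5 passed in each such fit. Of 368 list values 27, all of lists that had not passed, had the other direction. By fry with the block this was the mesenchymal list (0.787). With the replicate block these were the keratins, Myc E-box targets and p53 targets (0.986 each, and 0.994 with an estimated correlation), and after the GC and length correction the siRNA list (0.94, and 0.993 with the block). Without 1 library the direction turned at least once in 11 lists, with adjusted p from 0.342 to 0.77 (junctions), 0.575 to 0.993 (keratins), 0.262 to 0.897 (TGF-beta pathway), 0.323 to 0.993 (Myc E-box), 0.00313 to 0.92 (E2F), 0.000437 to 0.549 (mitotic), 0.521 to 0.938 (p53), 0.157 to 0.938 (NF-kappaB), 0.513 to 0.96 (corepressors), 0.0786 to 0.96 (unfolded protein) and 0.231 to 0.993 (siRNA). None of the turned values passed, and the cause was not tested.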

Other observations

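All gene groups in the first 2 paragraphs were chosen after their values were seen, as were the tests on siNTC replicate 3 other than thinning, the tests on retrocopies, Myc targets and leukocyte transcripts; the tests by GC and length correction, thinning and other splits were set before their results. Among 15 genes of secreted plasma proteins, picked after some of them had been seen to pass and not tested as a group, 8 rose, 3 fell and 4 did not pass (limma; 11 and 3 with the replicate block). The fibrinogen chains rose, Fga from 39.0 ± 38.8 to 255 ± 40.2 normalised read counts (log2 fold change 3.19 ± 0.66, adjusted p = 0.0434), Fgb from 292 ± 315 to 1926 ± 166 (log2 fold change 3.40 ± 0.75, adjusted p = 0.0487) and Fgg from 2.03 ± 1.94 to 30.9 ± 3.48 (log2 fold change 3.67 ± 0.63, adjusted p = 0.0282), as did the vitamin D binding protein Gc (from 4041 ± 1439.6 to 10749 ± 799.6; log2 fold change 1.47 ± 0.25, adjusted p = 0.0264) and the retinol binding protein Rbp4 (from 5968 ± 3379.9 to 15648 ± 1036; log2 fold change 1.53 ± 0.34, adjusted p = 0.0486). The orosomucoids, which are near-identical genes, fell: Orm1 from 1375 ± 209 to 759 ± 92.1 (log2 fold change -0.85 ± 0.16, adjusted p = 0.0326) and Orm3 from 419 ± 169.6 to 135 ± 30.1 (log2 fold change -1.58 ± 0.30, adjusted p = 0.0352). The acute phase gene Lcn2 was at 921 ± 692 and 748 ± 418 and Saa3 at 51.4 ± 57.2 and 148 ± 100.3 (adjusted p = 0.871 and 0.236; 0.0179 for Saa3 with the block).

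Among 16 genes of the circadian clock, also picked after values were seen and not tested as a group, 3 rose, 1 fell and 12 did not pass (7 and 4 with the replicate block). Period 2, Per2, rose from 648 ± 231 to 1901 ± 109 (log2 fold change 1.61 ± 0.23, adjusted p = 0.0195) and the cryptochromes Cry1 and Cry2 rose by log2 fold changes of 1.02 and 1.15 (adjusted p = 0.0217 and 0.0356), while the repressor Nr1d1 fell from 512 ± 37.1 to 254 ± 76.9 (log2 fold change -1.06 ± 0.23, adjusted p = 0.0493). Clock was at 3422 ± 271 and 2486 ± 158 (adjusted p = 0.0654; 0.0273 with the block) and Arntl at 649.6 ± 111 and 822 ± 115 (adjusted p = 0.27). All 21 genes that passed among these and the leukocyte-associated genes kept their sign under quantile normalization and after the GC and length correction. edgeR called 17 of the 21, and not Fga, Fgb, Rbp4 and Nr1d1 (adjusted p = 0.0602, 0.0787, 0.0687 and 0.0572). limma called 21 without siNTC replicate 3, 5 without siNTC replicate 2, 5 without siMnt replicate 3, and 0 without siNTC replicate 1, siMnt replicate 1 or siMnt replicate 2. A search of 199 families of at least 8 genes with the same symbol stem gave 11 past camera's threshold, 7 of them also with the replicate block and 9 after the GC and length correction. RNA polymerase subunits (Polr, 28 genes, median -0.25, adjusted p = 0.0132) and ribosomal proteins (Rpl, 51 genes, median -0.20, adjusted p = 0.0132) were lower, and Rassf genes (9 genes, median 0.58, adjusted p = 0.0132) higher. With an estimated correlation the unadjusted p was 0.236, 0.549 and 0.0203, and under quantile normalization the adjusted p was 0.0484, 0.221 and 0.0484.

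A control library lay toward siMnt. siNTC replicate 3 lay 0.588 of the way from the other controls to siMnt on the first principal component, still 0.588 after thinning to equal depth and 0.563 after the GC and length correction, which argues against depth. A siMnt library under a control label is argued against by its Mnt, 2.13 times that of the highest siMnt library, and siMnt RNA mixed into it, as the whole cause, by the same Mnt level, at -1.05 on a scale from 0 for the other controls to 1 for siMnt. Mixing would also move all genes by the same share, whereas the median position ran over 17 fixed lists from 0.107 for hypoxia genes to 1.09 for p53 targets (difference 0.987, permutation p = 5e-05 over genes, too small a value since genes of a list vary together). A shift shared with siMnt replicate 3 stays open: the difference within number 3 on that component, 0.385 of the smaller of the other numbers, restates the position of this control, and both libraries of number 3 deviated together (correlation 0.35 across genes). Of 28 TGF-beta and SMAD targets 18 were lowest among the controls there (64.3%), against 35.3% of other genes. Fisher's exact test over genes gave p = 0.00235. That restates the position of this control in part, since the list tended lower in siMnt. The median position of the list, 0.861, was near those of the epithelial (0.862), ribosome (0.832) and actin (0.919) lists. The test is thus not specific to TGF-beta. Id1 and Id3, which TGF-beta lowers in many epithelial cells, were among the 18 and go the other way. Genes of a list also vary together, so a lower response of that culture to TGF-beta stays open as an untested hypothesis.

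Glycolysis and hypoxia genes were higher in siMnt in all 3 replicate numbers. A trend with GC content or transcript length is argued against as the whole cause, the list median being 0.545 after its correction with 11 members past the threshold (camera with the preset correlation adjusted p = 7.6e-10, or 7.1e-09 with the replicate block). With an estimated correlation the uncorrected list did not pass (0.21, or 0.931 with the block). Reads shared with retrocopies of glycolytic enzymes are argued against as the whole cause by the 12 members that are not such enzymes. Their median was 0.697 (95% bootstrap interval over genes 0.259 to 1.39) with 5 past the threshold. This interval holds no spread between libraries. The 32 other Myc targets had a median of -0.122 with an upper bootstrap bound over genes of 0.09. That bound holds no spread between libraries. For all 34 targets the median within replicate numbers 1, 2 and 3 was -0.09, -0.20 and 0.12. A general rise of E-box genes of Myc was thus not seen across these targets. With all libraries Myc itself had a lower mean in siMnt, which passed with the replicate block and not without it. The targets therefore cannot isolate an effect of lower Mnt at E-boxes. A rise in this set of genes when Mnt is lowered remains a candidate explanation. The comparison holds siMnt against siNTC only, so an effect of lower Mnt cannot be told apart from any other effect of that siRNA. Whether siMnt cultures differed in density or oxygen was not tested, since the table holds no measure of either.

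Genes best known from leukocytes, Csf1r, Itgam, Cybb, Mpeg1, Irf8 and Inpp5d, were higher in siMnt; these 6 were picked because they rose. Cybb rose from 81.5 ± 61.3 to 636 ± 186 (log2 fold change 3.17 ± 0.50, adjusted p = 0.0242) and Irf8 rose from 34.6 ± 15.6 to 123 ± 33.7 (log2 fold change 1.86 ± 0.36, adjusted p = 0.0368). RNA from leukocytes is argued against as the source of 5 of them, all but Itgam: of 6 abundant leukocyte transcripts the largest rise was 0.113 of the smallest rise among the 5, and 6 of 6 lay under 10% of the Csf1r level in siMnt. Lyz2 was at 2.92 ± 0.85 in siNTC and 8.38 ± 3.496 in siMnt, Ptprc at 3.81 ± 2.69 and 3.09 ± 0.58, Coro1a at 4.40 ± 3.01 and 4.34 ± 1.96, Laptm5 at 148 ± 29.4 and 112 ± 31.2, and Cd68 at 190 ± 67.8 and 164 ± 45.8. Cd53, at 0 ± 0 and 8.03 ± 2.46, rose by 0.449 of the rise of Itgam, so a small amount of such RNA stays open for Itgam. The median log2 fold change of the 6 picked genes was 1.85 and after the GC and length correction 1.77, which argues against that trend. Expression by the NMuMG cells themselves may account for those 5 genes, as a hypothesis.

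Other splits of the 6 libraries into 3 against 3 number 10 with the real one, too few for a share under 0.05. The real split gave 494 genes and the highest other split 0, so 1 of 10 splits gave as many. With the replicate block, among the 4 splits that part all 3 pairs, the real split gave 1998 genes and the highest other 0, so 1 of 4 gave as many. In the other splits the siRNA difference adds to the spread within groups, so a low count there was likely beforehand. For the gene lists by camera with the preset correlation the real split gave 6 and the highest other 14, and 10 of 10 gave as many. Each other split sets unequal numbers of siNTC and siMnt libraries against each other, so it still holds part of the siRNA difference. Lists called there may reflect that part or structure shared by the genes of a list across libraries. The splits cannot tell these apart. Calls by the preset test for the 6 lists may also reflect such structure. By fry, which does not compare a list with other genes, the hypoxia list had adjusted p = 0.00603, and 0.131 with the replicate block.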
